A study of Drosophila melanogaster with 3 samples.

How the data were processed

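CG6175-eGFP was mapped by anti-GFP ChIP-seq in whole embryos aged 0 to 24 h, in 3 samples that the labels number as biological replicates of 1 group; nothing in them says how separately the embryos were collected, so errors over replicates measure the spread between these samples. The labels name a possible control experiment, which is not analysed here. Per the labels, the assembly is dm6. The aligner, the peak caller and their versions are not given in the sources used here. The depth is unknown, because no file gives read counts, so no interval from read depth can be given; Wilson and odds ratio intervals (95%) cover counting of regions or genes only.

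For each replicate and for the whole series the authors deposited a ranked list of candidate regions and a list that passed a threshold on the irreproducible discovery rate (IDR). The score of each region is the authors' own, a scaled negative log of the global IDR of at most 1000, and the lowest score in the lists that passed is 830 or 831. The signal of each region is the authors' own value with no scale stated, and was used only to describe, rank or filter regions within a list and to correlate replicates, by rank and, as an alternative, by value on the log2 scale. The ranked lists also hold the -log10 of the global IDR as deposited by the authors, and the value 2 marks the threshold of 0.01. Each replicate's regions were called per sample, and the whole-series lists combine samples. From the records they share, the candidates behind the conservative list matched member records of replicates 1 (73.7%) and 2 (81.3%) and none of replicate 3, so its agreement with replicates 1 and 2 is not independent. The authors' notes list the alignments of all 3 replicates as inputs of the whole-series lists, so its agreement with replicate 3 may not be independent either. There were 102 candidates past the threshold that are absent from the conservative list, and they were left out of both the main set and the background.

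The conservative list was the main set, as fixed before the data were examined, and the 120506 candidates of its ranked list that did not pass were the background. Overlap needed at least 1 bp. Chance overlap came from 1000 seeded draws that placed each replicate's regions on random candidates of its own ranked list. Genes and TSSs were taken from Ensembl annotation BDGP6.54, release 115, without transposable elements; its chromosome arms have the lengths of the reference sequence, and both were checked against the coordinates of the lists. The 5′ end of each annotated transcript was taken as a TSS, for noncoding RNA genes too. A summit within 500 bp of a TSS was called promoter, and other summits were placed, in order, in 5′ UTR, coding exon, 3′ UTR, other exon, intron or intergenic sequence. Promoter share, classes, arms, gene lists and motifs were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family, passing under 0.05. Gene lists counted genes with a main-set summit at a TSS among genes with a candidate summit there. Older names in the lists that could mean more than 1 gene were settled by hand, and microRNA genes were taken by name, since the annotation files them with other noncoding RNA. Motifs (34, of which 2 are scrambled controls) were searched on both strands within 50 bp of the summit, as was every 6-base sequence with its reverse complement; GC matching used bins of 5%.

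The named genes follow a rule set before the data were examined. It takes the gene with the TSS nearest to each of the 25 strongest main-set regions found in all 3 replicates, CG6175, the 4 members with the strongest summit within 500 bp in each list that passed, and up to 2 in other lists.

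On simulated regions a planted promoter odds ratio of 3 was recovered as 2.93 (2.7 to 3.17), and a GATA site planted at 3 as 3.48 (2.94 to 4.11) with 0 other motifs called. Proteasome genes planted with a weight of 10 gave an odds ratio of 18.8, with 1 other list called. In 20 draws of 2672 regions without an effect, calls numbered 2 of 20 for promoters, 0 of 140 for classes, 1 of 160 for arms, 2 of 700 for lists and 0 of 680 for motifs. Simulated independent lists overlapped by 1.36% against 1.13% by chance.

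For results on the main set, leaving out a replicate meant keeping the main-set regions held by the own lists of both others, which changes the set as well (873, 881 and 1191 regions). Alternatives covered leaving out each replicate, other region sets, thresholds, windows, overlap rules and backgrounds. Those added after seeing the data were a global IDR of 0.001 and 0.05, removal of regions of signal under 20, joining of summits within 360 bp, chromosome arms alone, GC matching of promoters and classes, the 5′-most TSS and protein-coding genes alone. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.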

Results

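The DNA bound by an eGFP-tagged copy of CG6175 was mapped in whole Drosophila melanogaster embryos collected from 0 to 24 h after egg laying. Transgenic flies carried the CG6175-eGFP fusion, chromatin was sheared by sonication to 200 to 800 bp, and the fragments were recovered with an anti-GFP antibody (ChIP-seq). The labels give 1 group of 3 biological replicates. Each replicate has a list of regions that passed the authors' threshold and a longer list of ranked candidates, and 4 further pairs of such lists cover the whole series. The number of reads behind each list is unknown, because the files hold no read counts. The annotation used here lists CG6175 under the name Dyro. The labels state no question beyond the map itself, so the comparisons ask where the regions lie, whether the replicates share them, and which genes and sequences they carry.

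Regions at Dyro, Ugalt, CG14100 and CG11050 were the strongest of the series and passed the threshold in all 3 replicates. The replicates held 2008, 1636 and 1151 regions (mean 1598 ± 429.7, SD, n = 3), out of 101330 to 112353 candidates each. The largest list was 1.75 times the smallest. On average 63.1% ± 13.6 (SD over the 6 ordered pairs) of the regions of a replicate overlapped a region of another by at least 1 bp. The share ran from 43.5% of the regions of replicate 1 found in replicate 3 to 76.6% of those of replicate 3 found in replicate 1. Placing the regions on randomly chosen candidates gave 1.15% on average and 1.67% at most over 1000 draws (permutation p = 0.001, one-sided, the smallest these draws can give).

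The conservative list of the whole series, used as the main set, held 2672 regions, and the largest whole-series list held 3694, 1.38 times as many. Of the main set, 63.1% overlapped a region of replicate 1, 56.3% of replicate 2 and 38.4% of replicate 3, against 0.462%, 0.267% and 0.194% of candidates that did not pass. Since its candidates matched records of replicates 1 and 2, their contrast was partly fixed by how the main set was chosen. The lower share of replicate 3 may reflect that choice. Its own list was also the shortest, with 1151 regions against 2008 and 1636, which limits the share it can hold. These were not told apart from a weaker sample. All 3 replicates held 792 of the 2672 regions (29.6%), and 606 were in no replicate's own list. Across these regions, which are not independent replicates, the signal of 1 replicate correlated with that of another with a Spearman rho of 0.641 (replicates 1 and 2), 0.66 (1 and 3) and 0.724 (2 and 3).

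The region with the highest signal in the main set lay at the promoter of the tagged gene itself. Dyro spans 3L 11287936 to 11295919 on the minus strand. The region covered 3L 11295549 to 11296275, with its summit 45 bp from the annotated start at 11295919 and a signal of 1924. It ranked 3 of 2008 in replicate 1, 1 of 1636 in replicate 2 and 5 of 1151 in replicate 3, and 1 in each of the whole-series lists. The reference sequence around this summit, 3L 11295944 to 11295984, is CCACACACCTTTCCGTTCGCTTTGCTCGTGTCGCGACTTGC. Another 5 main-set regions fell in the gene and 500 bp around it: 1 at the inner promoter (signal 776.5), 3 in introns (805.3, 477.2 and 388.0) and 1 in a coding exon (131.9). Candidates from 500 bp to 20 kb on either side of the gene also had a higher median signal, 68.3, than 99.9% of windows of that length on 3L. Windows that overlap this locus were not left out of that comparison.

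**Figure D1:**
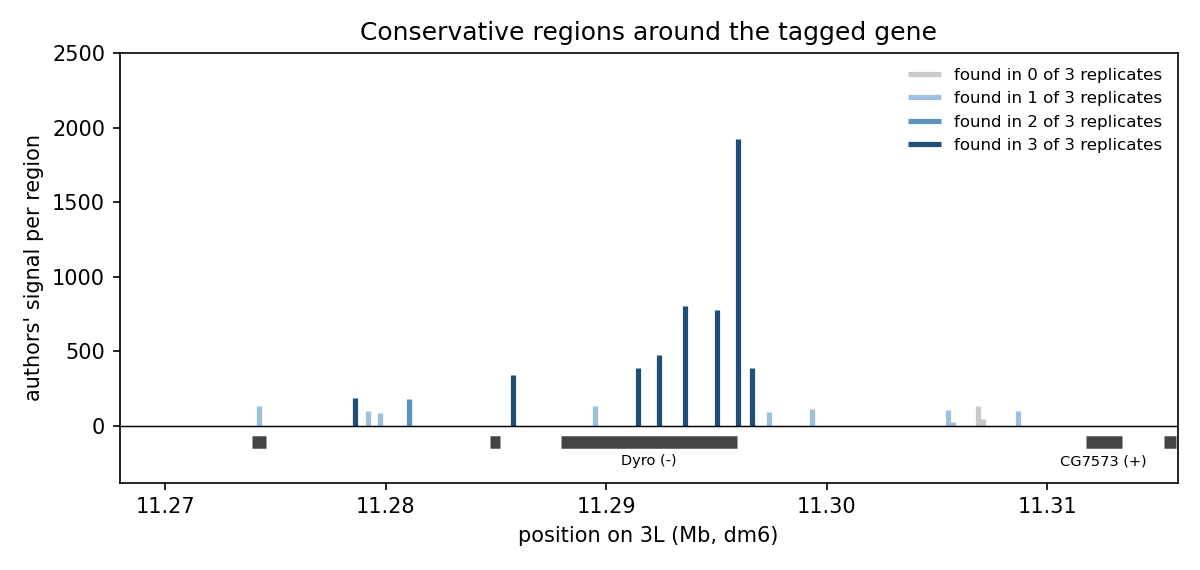
Position on 3L (Mb, dm6) against the authors' signal of each main-set region within 20 kb of Dyro, coloured by the number of replicates whose own list holds it. Grey bars below 0 are annotated genes. The 1924 signal stands at the 5′ end of the gene, and the next highest, 805.3 and 776.5, lie inside it.

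The 25 strongest regions found in all 3 replicates had signals of 899.5 to 1924, and 20 of them had a summit within 500 bp of a transcription start site (TSS). After Dyro came Ugalt, which encodes a UDP-galactose transporter (X 2703714 to 2704056, 1906, 39 bp from the TSS), CG14100 (3L 19590462 to 19590783, 1851, 99 bp) and CG11050 (2L 6612533 to 6612905, 1815), where the summit lay in an intron 1024 bp from the nearest TSS. Among the next were mRpL41, for a protein of the mitochondrial ribosome (2R 15217588 to 15217912, 1472), PNPase, for the mitochondrial polynucleotide phosphorylase (3R, 1081), and mRpL23 (3L, 972.3). The 25 also held ph-p, a Polycomb gene (X, 1222, 493 bp from a TSS), RasGAP1, for a Ras GTPase-activating protein (3L, 1095), Akt, for a kinase of the insulin pathway (3R, 1067, in an intron) and Adf1, for a transcription factor (2R, 914.0, in an intron). The arginine methyltransferase gene Art3 (3R, 1176) and the tubulin acetyltransferase gene Atat (3L, 961.1) also belonged to this group. The rest were NaPi-III (1373), Tcs5 (1369), CG5001 (1281), CenG1A (1152), asRNA:CR45928 (1104), CG7601 (1093), CG1628 (1078), CG5611 (1075), CG32772 (1006, in an intron 1261 bp from a TSS), MFS10 (971.0), lncRNA:CR44619 (946.9) and CG9663 (899.5, in an intron 932 bp from a TSS). In 10 of the 25, the TSS of another gene also lay within 500 bp, as at Art3 with mRpS10, CenG1A with mRpS23 and asRNA:CR45928 with eIF6.

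Promoters held most of the main set, and exons of protein-coding sequence held almost none of it. A summit within 500 bp of a TSS was found in 1375 of 2672 regions (51.5%, 95% Wilson interval 49.6 to 53.4) against 15.5% of the 120506 candidates that did not pass (odds ratio 5.78, 95% interval 5.35 to 6.25). Over the replicates the promoter share was 54.5% ± 2.67 (SD, n = 3) against 15.6% ± 1.85 of their other candidates. Coding exons held 1.76% of the main set against 24.3% (odds ratio 0.0557, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 1.00e-241), 3′ UTRs 0.711% against 1.98% (0.355, adjusted p = 3.25e-07), intergenic sequence 11.8% against 20.9% (0.506, adjusted p = 4.98e-34) and introns 31.9% against 35.3% (0.86, adjusted p = 4.05e-04). The coding exon odds ratio was 0.0215, 0.0285 and 0.0343 in main-set regions held by both other replicates without replicates 1, 2 and 3, and 0.0237 in those held by all 3. The intron call ended with a TSS window of 250 bp (odds ratio 0.966, Fisher's exact adjusted p = 0.46). The shares of 5′ UTRs (1.12% against 1.1%) and other exons (1.2% against 0.841%) did not pass the test. Promoter summits of the main set sat at a median of -73.0 bp from the TSS (interquartile range -159.0 to 15 bp), and 71.8% lay upstream against 38.04% of promoter candidates that did not pass (odds ratio 4.14, 95% interval 3.67 to 4.68, Fisher's exact p = 5.50e-132). A paired exact permutation over 3 replicates cannot go below p = 0.25 (two-sided), so the promoter test is over regions.

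**Figure D2:**
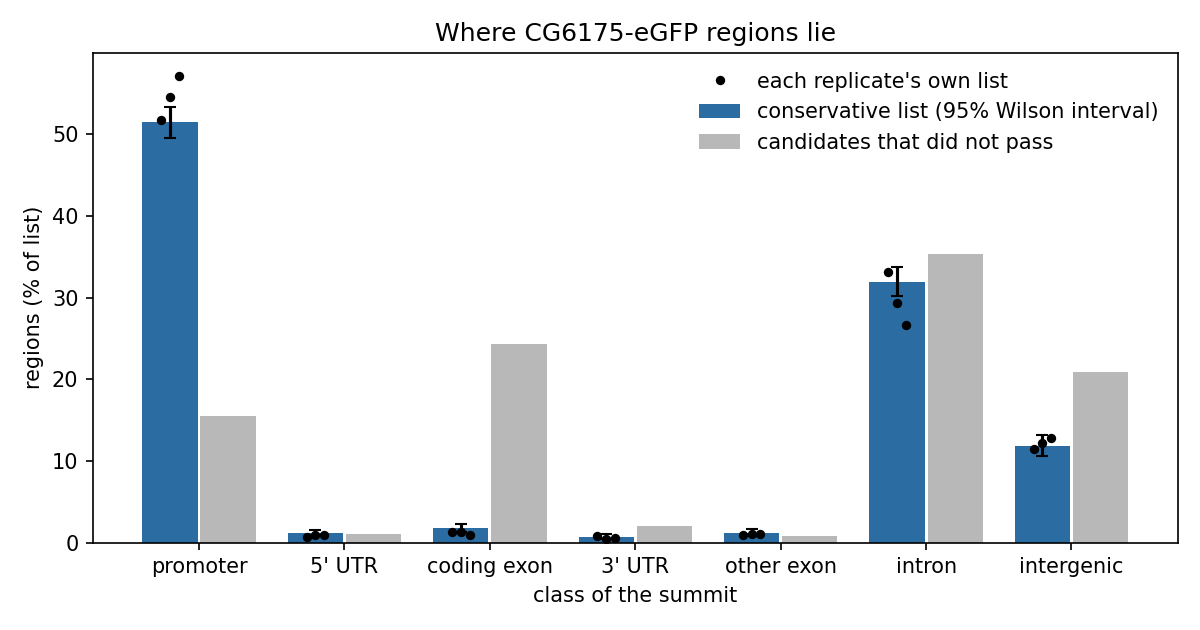
Share of regions (%) in each class of the annotation for the main set (blue bars, 95% Wilson interval), each replicate's own list (points) and the candidates that did not pass (grey bars). Promoters hold 51.5% against 15.5%, and coding exons 1.76% against 24.3%.

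Ribosomal protein genes stood out among the 35 gene lists. A main-set summit lay within 500 bp of a TSS at 45 of 82 ribosomal protein genes (54.9%) against 12.1% of other genes (odds ratio 8.85, 95% interval 5.71 to 13.7, Fisher's exact test with Benjamini-Hochberg adjustment over the lists, adjusted p = 7.59e-19). The odds ratio was above 1 in 3 of 3 replicates, with 40.6% ± 7.11 (SD, n = 3) of the list's genes against 8.72% ± 1.11 of others. The strongest were RpS27 (3R 25247386 to 25247644, signal 636.7), RpL7 (2L 10200921 to 10201140, 477.9), RpL34b (3R 9401183 to 9401403, 396.3) and RpL14 (3L 8600859 to 8601064, 367.6). At each of these 4 another gene also had a TSS within 500 bp, such as Nelf-E at RpL14. The own list of replicate 3 did not hold the region at RpL7. In all, 1623 of the 13141 genes with a candidate at a TSS had a main-set summit (12.35%), and 6 of the 35 lists passed, 3 of them higher and 3 lower.

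Cuticle and epidermis genes had no main-set summit at all: 0 of 81, which allows a share of up to 3.7% (Fisher's exact adjusted p = 8.65e-04). Both values treat the genes as independent, which neighbouring genes of 1 family may not be. In the own lists of replicates 1, 2 and 3 the counts were 1 of 70, 0 of 77 and 0 of 78 (Fisher's exact adjusted p = 0.0802, 0.0115 and 0.0486). MicroRNA genes were lower at 6 of 168 (3.57%, odds ratio 0.26, 95% interval 0.115 to 0.589, Fisher's exact adjusted p = 0.00149), with mir-4968 (527.8), mir-314 (456.3), mir-9377 (159.2) and mir-9378 (118.6) the strongest. The summit counted for mir-4968 lay 495 bp from its TSS, and a TSS of Mob2 also lay within 500 bp. The summits at mir-4968, mir-9377 and mir-9378 lay within Mob2, Tis11 and CG17124, in that order. For a microRNA gene the TSS used here is the 5′ end of its annotated transcript, which need not be where transcription begins. The microRNA count is thus not shown to be one of promoters. Transfer RNA genes were lower at 8 of 152 (5.26%, odds ratio 0.391, 95% interval 0.192 to 0.799, Fisher's exact adjusted p = 0.0454), led by the genes tRNA:Tyr-GTA-1-8 (224.8), tRNA:Phe-GAA-1-2 (194.1), tRNA:Pro-AGG-1-1 (161.9) and tRNA:Trp-CCA-2-2 (137.7). At tRNA:Tyr-GTA-1-8, tRNA:Phe-GAA-1-2 and tRNA:Trp-CCA-2-2 a TSS of CG8036, RpL17 and CG30122, in that order, also lay within 500 bp. Of all genes that are not protein-coding, 5.99% had a main-set summit (157 of 2622), close to the tRNA share. The tRNA and microRNA lists were not tested against these genes alone. Ecdysone pathway genes were higher at 7 of 20 (35.0%, odds ratio 3.83, 95% interval 1.53 to 9.62, Fisher's exact adjusted p = 0.0454): E23, for an ecdysone-induced transporter (370.2), the early response genes Eip74EF (264.6) and Eip75B (137.0), and Cyp18a1, for an enzyme that breaks ecdysone down (113.2), were the strongest. Cytoskeleton genes were higher at 6 of 15 (odds ratio 4.75, 95% interval 1.69 to 13.4, Fisher's exact adjusted p = 0.0454), with shot (221.5), sqh, for the light chain of myosin (175.8), Moe (164.6) and alphaTub84B (140.4). No replicate's own list held the alphaTub84B region. Only replicate 1 held that of Cyp18a1, only replicate 2 that of mir-9378 and only replicate 3 that of tRNA:Trp-CCA-2-2. Replicate 3 lacked those of sqh, Moe, Eip75B and tRNA:Pro-AGG-1-1, and replicate 2 that of tRNA:Phe-GAA-1-2. Leaving out a replicate also limits the main set to regions held by both others (873, 881 and 1191 without replicates 1, 2 and 3). In these smaller sets ribosomal protein genes passed with odds ratios of 5.31, 5.38 and 7.51, as they did in the 792 regions held by all 3 (4.74). The ecdysone (odds ratio 1.92 to 2.49, adjusted p from 0.453 to 0.69, and 0.653 in all 3) and cytoskeleton calls (1.23 to 3.53, adjusted p from 0.295 to 0.857, and 0.881) ended in each of them. The cuticle and microRNA calls ended in the sets without replicate 1 (0.154 each) and 2 (0.137 and 0.162) and in all 3 (0.242 and 0.305), and the tRNA call in that without replicate 2 (0.137) and in all 3 (0.0859). Cuticle genes still had no summit there, microRNA genes had odds ratios of 0.31 to 0.346, and those of tRNA genes, 0.231 and 0.126, lay further from 1 than in the main set. With the 5′-most TSS of each gene cytoskeleton genes turned to an odds ratio of 0.701 (Fisher's exact adjusted p = 1) and the ecdysone (2.41, 0.37) and tRNA calls (0.464, 0.155) ended. With TSS windows of 250 and 1000 bp and in the largest list, adjusted p was 0.0824, 0.0642 and 0.247 for ecdysone and 0.148, 0.06 and 0.103 for cytoskeleton genes. With the windows the odds ratios changed less, to 3.38 and 3.44 for ecdysone and 3.48 and 4.26 for cytoskeleton genes, and in the largest list they were 2.2 and 3.3. The tRNA call also ended at 1000 bp (0.528, 0.06) and, with an odds ratio of 0.25, at a global IDR of 0.001 (0.0618).

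Apart from cuticle and epidermis genes, lists of embryonic patterning and tissue genes did not pass the test in the main set. Dorsoventral patterning genes (6 of 17, Fisher's exact adjusted p = 0.065; brk 424.3, dpp 216.2), Polycomb and trithorax genes (6 of 18, 0.0765; ph-p 1222, brm 709.1) and muscle genes (5 of 15, 0.115; Msp300 273.9, tin 233.4) came nearest. Genes of the Notch pathway (5 of 16, 0.123; mam 201.7), of the Wnt, Hedgehog and Dpp pathways (6 of 21, 0.123), proneural and neuroblast genes (5 of 17, 0.137; grh 498.7, numb 253.3) and insulator proteins (4 of 12, 0.137; Chro 873.5, Cp190 275.2) followed. Dorsoventral genes passed against all annotated genes, at an IDR of 0.05 and with the 5′-most TSS. Muscle genes passed in the largest list and at an IDR of 0.05, Polycomb genes against all annotated genes, and Wnt, Hedgehog and Dpp genes with a window of 1000 bp. In the own lists of replicates 1, 2 and 3, the Wnt (0.048), dorsoventral (0.0115) and Polycomb genes (0.0494), in that order, passed by Fisher's exact test. Counts were 4 of 14 for heat shock genes (Hsp27 463.3, Hsp83 276.0), 4 of 23 for JAK-STAT and Hippo genes (sd 374.4), 3 of 17 for pair-rule and segment polarity genes (ptc 198.3), 2 of 14 for maternal and gap genes (nanos 165.2, bcd 141.6), 1 of 5 for Hox genes (Abd-B 205.8) and 2 of 19 for EGFR and FGF genes (spi 425.6). They were 3 of 17 for germline and piRNA genes (bgcn 210.7), 2 of 12 for gut genes (bowl 264.1), 2 of 9 for tracheal genes (serp 139.1), 1 of 16 for neuronal genes (elav 382.9), 1 of 10 for glial genes (moody 642.4), 0 of 15 for blood cell genes, which allows up to 20%, 1 of 8 for clock genes (sgg 243.9) and 3 of 25 for immune effector genes (cact 178.4). Among housekeeping lists, translation factors had 8 of 37 (eIF6 1104), mitochondrial ribosomal proteins 8 of 65, cell cycle genes 4 of 30 (Dp 290.9), oxidative phosphorylation genes 4 of 63 (ND-ASHI 320.1) and proteasome genes 1 of 37 (Rpn3 118.9). Histone genes had 0 of 7, which allows up to 42.9%, snRNA genes 3 of 17 (snRNA:7SKa 177.3) and snoRNA genes 13 of 167 (snoRNA:Psi28S-2949 323.8). From heat shock genes on, the Fisher's exact adjusted p of the lists ran from 0.184 to 1.

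**Figure D3:**
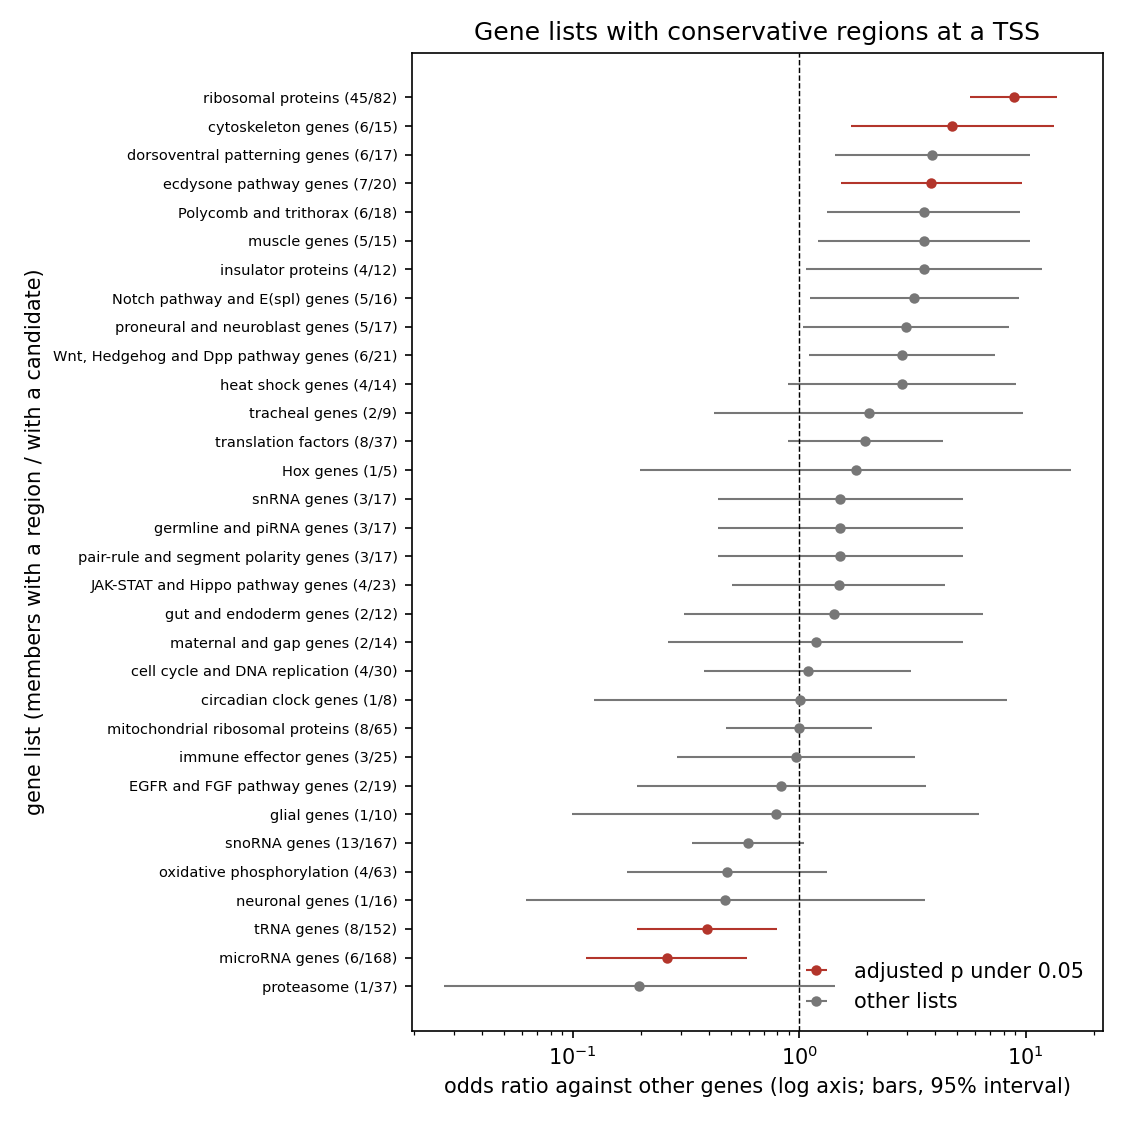
Odds ratio (log axis) of a main-set summit at a TSS for each gene list with at least 1 such gene, against all other genes with a candidate, with 95% intervals; counts stand beside each name. Ribosomal proteins lie at 8.85, and microRNA genes at 0.26.

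The DNA replication-related element (DRE, TATCGATA), a site of core promoters, was among the 18 of 34 sequence motifs that passed the test. Within 50 bp of the summit it occurred in 34 regions (1.27%) against 0.181% of candidates that did not pass (odds ratio 7.12, 95% interval 4.95 to 10.2, Fisher's exact test with Benjamini-Hochberg adjustment over motifs, adjusted p = 1.09e-15). Its odds ratio was 6.41, 4.42 and 5.15 in main-set regions held by both other replicates without replicates 1, 2 and 3, and 4.92 in those held by all 3. All 34 regions were at promoters, so none of the 1292 others carried it. The CTCF core occurred in 30 regions (1.12% against 0.265%, odds ratio 4.29, 95% interval 2.94 to 6.25, Fisher's exact adjusted p = 1.75e-09), the GAGA element in 84 (3.15% against 1.37%, 2.35, adjusted p = 1.58e-10) and the TATA box in 79 (2.96% against 1.22%, 2.48, adjusted p = 7.32e-11). CGATAG, which shares CGATA with the DRE but ends in a base beyond it, occurred in 129 (4.84% against 2.28%, odds ratio 2.17, Fisher's exact adjusted p = 6.04e-13). Its calls are thus not calls of the DRE itself, although a DRE followed by a G holds both. How many of the 129 regions carried both was not counted, so the 2 calls are not shown to be separate. The GATA site (3.52% against 1.83%), the Grainy head site (odds ratio 2.48), Motif 1 (2.57), Ohler motif 6 (3.5), Ohler motif 7 (1.93), the Mad site (1.43), the Sp/KLF GC box (1.74), the CA repeat (1.59), the GAGAG core (1.31), the homeodomain site TAATTA (1.36) and the poly-A tract (1.5) were higher too. The Pho core (0.602, Fisher's exact adjusted p = 1.54e-07) and the E-box CAGCTG (0.774, adjusted p = 0.00871) were lower. Both scrambled controls did not pass (Fisher's exact adjusted p = 0.168 and 0.72). The scrambled DRE did pass with a window of 100 bp, and in the own list of replicate 2 (odds ratio 3.03, Fisher's exact adjusted p = 0.0129). Motif calls of similar size are therefore less secure.

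Motifs were also tested within promoter regions and within the others. Among promoter regions 9 motifs passed, including the DRE (2.47% against 0.734%, odds ratio 3.43, Fisher's exact adjusted p = 2.63e-07) and CGATAG (2.11, adjusted p = 2.72e-09). Among the other regions 10 passed, led by the CTCF core (1.55% against 0.255%, odds ratio 6.14, Fisher's exact adjusted p = 1.12e-08), the Grainy head site (3.51, adjusted p = 5.63e-06), the Sp/KLF GC box (2.76, adjusted p = 2.85e-08) and the GATA site (2.75, adjusted p = 1.85e-09). The GAGA element (odds ratio 1.59 in promoters and 2.45 elsewhere), the TATA box (2.14 and 2.02), the CA repeat (1.51 and 1.72) and the poly-A tract (1.8 and 1.43) passed in both. Within promoters and against GC-matched candidates only CGATAG passed (2.55). The TATA box (0.941) and the poly-A tract (0.888) turned below 1 there, and the GAGA element (2.035, Fisher's exact adjusted p = 0.078), the CA repeat (1.5, 0.221) and the DRE (2.03, 0.132) did not pass. The odds ratio fell for the DRE but not for the GAGA element, and that of the CA repeat hardly changed, so these 2 lost calls do not show that GC content was their source. Whether these odds ratios differ between promoter and other regions was not tested. Summit sequences were poorer in GC (43.9%) than candidates that did not pass (48.9%). Against candidates matched on GC content, 13 motifs passed, among them CTCF (odds ratio 5.05), the DRE (4.58), CGATAG (3.18), the GAGA element (2.81) and the Sp/KLF GC box (2.53). The TATA box (1.3, Fisher's exact adjusted p = 0.162), Ohler motif 6 (1.67, 0.651), the E-box CAGCTG (0.954, 0.75), the homeodomain site (0.814, 0.102) and the poly-A tract (0.816, 0.102) did not. The regions' own flanks were 2 windows per region, 200 to 300 bp from the summit on either side. Each flank counted as a region of its own and was not paired with its summit. They lie within the sheared fragment length of 200 to 800 bp, which limits what a lost call means. Against the regions' own flanks the calls of the Grainy head site (1.46, adjusted p = 0.297), the TATA box (1.18, 0.511), the GATA site (1.17, 0.504), Motif 1 (1.28, 0.773), Ohler motif 6 (1.67, 0.773), the CA repeat (1.22, 0.297) and the Pho core (0.759, 0.0685), by Fisher's exact test, ended. The GAGA element (0.818), the GAGAG core (0.997), the E-box CAGCTG (1.03), the homeodomain site (0.975) and the poly-A tract (0.729, Fisher's exact adjusted p = 0.00752) turned to the other side of 1 there. The smaller sets held by both other replicates gave no call for the GATA (adjusted p from 0.0501 to 0.0721), Motif 1 (0.0512 to 0.259) and Mad sites (0.069 to 0.26). The odds ratio of the GATA site was 1.53 to 1.58 there, and that of the Mad site, 1.42 to 1.58, stayed near the main value. The DRE (1.79 to 2.58, adjusted p from 0.0558 to 0.472), GAGA (1.05 to 1.26, 0.637 to 1) and CA repeat (0.952 to 1.28, 0.595 to 1) calls within promoters ended in each of them as well. Over all regions GAGA, GAGAG, Ohler motif 7 and the CA repeat lost their calls in the sets without replicate 1 (0.0687 to 0.662) and 2 (0.212 to 0.619), with odds ratios of 1.11 to 1.61. Ohler motif 6 (0.0576) and the E-box CAGCTG (0.138) lost theirs in the set without replicate 3, although the odds ratio of the former rose to 4.71 and that of the latter, 0.79, stayed near the main value. Ohler motif 6 rested on 5 main-set regions, and its odds ratio was 6.44 and 6.38 in the sets without replicates 1 and 2.

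**Figure D4:**
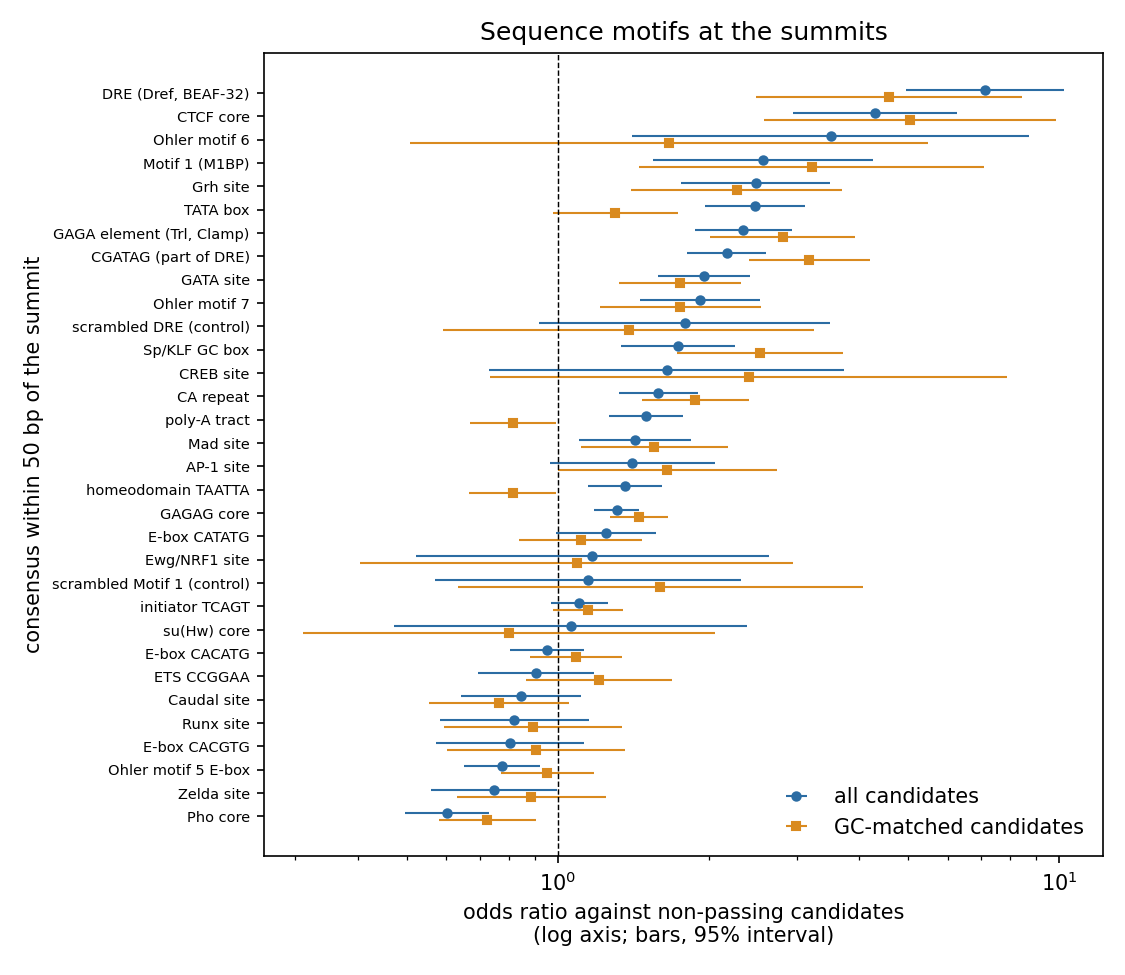
Odds ratio (log axis) of each motif within 50 bp of the summit, with 95% intervals, for motifs found in at least 5 regions: blue circles against all candidates that did not pass, orange squares against candidates matched on GC content. The DRE lies at 7.12 and 4.58, and the CTCF core at 4.29 and 5.05.

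Of all 6-base sequences, 1090 of 2080 differed from the other candidates, 462 higher and 628 lower, and 494 against GC-matched candidates, 217 higher and 277 lower. AT-rich words such as TTAAAA led the higher ones (19.1% against 8.18%, odds ratio 2.65). With GC matched, CGATAG (4.84% against 1.57%), AGAGCG (6.86% against 3.17%), GGGGCA (8.36% against 4.27%) and ACAGTG (8.29% against 4.33%) were among the higher ones, and CCAGGA (0.712% against 5.51%) led the lower ones.

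Regions were spread over the large chromosome arms. Arms 2R (20.9% of regions against 18.7% of other candidates, odds ratio 1.15, adjusted p = 0.00668) and 3L (21.8% against 19.4%, 1.16, adjusted p = 0.00637) held more, and 3R (21.9% against 25.03%, 0.838, adjusted p = 6.39e-04) and contigs outside the arms (0.187% against 0.94%, 0.197, adjusted p = 2.34e-05) held fewer, by Fisher's exact test. The shares of 2L (17.4% against 17.3%) and X (17.8% against 18.5%) did not pass the test, and 4 and Y held 0 regions. In main-set regions held by all 3 replicates none of these passed (adjusted p from 0.0694 to 1), nor in those held by replicates 2 and 3 (0.136 to 0.799). In all 3 the odds ratios of 2R (1.15), 3R (0.819) and the other contigs (0.133) were about as far from 1 as in the main set or further, and that of 3L fell to 1.01. Among those held by replicates 1 and 3 only the other contigs passed, and among those held by replicates 1 and 2 all but 3L did (0.155). In the own lists of replicates 1, 2 and 3 the other contigs did not pass (Fisher's exact adjusted p = 0.25, 0.111 and 0.451). Replicate 3 went the other way there (2.085% against 1.503%, odds ratio 1.4).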

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

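The count below came from a comparison chosen after the lists were seen. A set of 102 candidates had a global IDR of 0.01 or less in the ranked list and yet were missing from the conservative list, a signal in data outside the main set, with no control samples to compare. Of these regions 58 lay on 3R, 34 on 2L, 6 on 2R and 2 on 3L, and 2 outside the arms. Their signals had a median of 163.4 and reached 1584. Summits within 20 kb of one another formed 42 groups, the largest with 17 regions. Each replicate's ranked list also held regions past the threshold that its own thresholded list left out: 87, 83 and 88. Of the 102, 75 were overlapped by such a region in replicate 1, 74 in replicate 2 and 48 in replicate 3. The sources used here do not say why these regions were left out, and no explanation was tested.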

How the results depend on the processing

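Promoter share (odds ratio 4.54 to 8.63) and replicate overlap (52.6% to 69.0%) kept their direction and passed their test under every alternative run, as did the ribosomal protein genes, and the number of feature classes past the test stayed within 1.5 times the main count. The planned limit of a global IDR of 0.01 removed no region, since the deposited lists already meet it. Alternatives at an IDR of 0.001 or 0.05, without signals under 20, with joined summits, on the arms alone, with GC matching of promoters and classes, with the 5′-most TSS and over protein-coding genes were chosen after seeing the data. No paired analysis was possible because the labels give only 1 group, so no samples of different groups share a replicate number. Unknown depth limits what a missing region can mean. The cause was not tested below, except that a stricter IDR leaves fewer regions (1322 at 0.001), and that leaving out a replicate keeps only main-set regions held by both others (873 to 1191, and 792 in all 3), so a lost call there is not shown to come from the replicate left out. Of 546 values of single classes, arms, lists and motifs under the alternatives, 403 kept their direction and call, 126 lost the call and 17 reversed. The 403 include the values at the planned IDR limit of 0.01, which could not change because it removed no region.

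Regions per replicate averaged 849.7 at an IDR of 0.001 and 2639.7 at 0.05. Mean signal correlation was 0.641 to 0.724 when each replicate was left out, 0.784 as Pearson r and 0.576 over the largest list. Arms past the test numbered 0 to 3 when each replicate was left out, 0 for regions in all 3 replicates, 2 at an IDR of 0.001 and 7 at 0.05. Gene lists past the test numbered 1 to 5 when each replicate was left out, 2 in all 3 replicates, 3 at an IDR of 0.001 and 2 over protein-coding genes. Of lists not called in the main set, insulator proteins passed under 5 of the alternatives. Dorsoventral patterning, muscle, Polycomb and trithorax, histone, and Wnt, Hedgehog and Dpp genes passed under fewer. Motifs past the test numbered 11 for regions in all 3 replicates and 7 against the regions' own flanks. Within promoters they numbered 4 when each replicate was left out, 4 in all 3 replicates, 15 with a window of 100 bp, 5 against own flanks, 1 against GC-matched candidates and 4 at an IDR of 0.001.

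Cytoskeleton genes reversed with the 5′-most TSS (odds ratio 0.701). Against own flanks the GAGA element (0.818), GAGAG core (0.997), E-box CAGCTG (1.03), homeodomain site (0.975) and poly-A tract (0.729) reversed, as did GAGA (0.808), homeodomain (0.935) and poly-A (0.912) within promoters. Against GC-matched candidates the homeodomain site (0.814) and poly-A tract (0.816) reversed, and within promoters the homeodomain site (0.84), TATA box (0.941) and poly-A tract (0.888). Within promoters Ohler motif 7 reversed without replicates 1 and 2 and the CA repeat without replicate 2 (0.969 to 1.74 and 0.952 to 1.28 when each replicate was left out).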

Other observations

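The tests in this part were chosen after the results were seen, except the ribosomal protein and gene body tests; the GC-matched promoter test was added after the data were seen, with its bounds written before its result. Promoters shared by neighbouring genes were common in the main set. TSSs of more than 1 gene lay within 500 bp of the summit at 420 of 1375 promoter regions (30.5%) against 15.3% of promoter candidates that did not pass (odds ratio 2.44, 95% interval 2.16 to 2.76, Fisher's exact test with Benjamini-Hochberg adjustment over 4 descriptions, adjusted p = 9.40e-42). Main-set promoter summits also lay upstream of the TSS more often (71.8% against 38.04%). The comparison was not matched on that position, so how much of the difference follows from it is not known. Protein-coding genes had a main-set summit at a TSS more often than other genes (13.9% against 5.99%, odds ratio 2.54, Fisher's exact adjusted p = 3.99e-32). Noncoding RNA genes (5.99% against 13.6%, odds ratio 0.404, Fisher's exact adjusted p = 2.04e-26) and pseudogenes (2 of 95, odds ratio 0.152, adjusted p = 7.78e-04) had one less often.

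Stronger regions were at promoters more often. Of the 534 regions with the highest signal, 333 were at promoters (62.4%, 95% Wilson interval 58.2 to 66.4), and of the 535 with the lowest, 238 (44.5%, 40.3 to 48.7). All 3 replicates held 92.9% of the former and 6.73% of the latter. In the 3 groups of 534 or 535 regions between them the share was 42.1%, 5.23% and 1.31%, so it did not fall steadily. The group with the lowest signal holds the 120 regions under 20 described below, nearly all overlapped by a stronger candidate. The 1292 regions away from promoters lay a median of 2060.5 bp from the nearest TSS (309 of them over 5 kb).

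The promoter share may owe something to how chromatin is recovered rather than to CG6175. AT-rich sequence is not the whole reason, since against GC-matched candidates the promoter odds ratio was 4.96 (4.47 to 5.5). Nonspecific recovery of highly transcribed genes stays open, because ribosomal protein genes, with an odds ratio of 8.85 (4.74 in regions held by all 3 replicates), had the excess it predicts. Of other widely transcribed lists, with intervals that include 1, translation factors (21.6% against 12.3% of other genes, interval of the odds ratio 0.896 to 4.3) lay above 1, mitochondrial ribosomal proteins at 0.996 (0.474 to 2.09), and oxidative phosphorylation (0.48, 0.174 to 1.32) and proteasome genes (0.197, 0.0269 to 1.44) below. Of lists that passed, cytoskeleton genes lay above 1 (4.75, 1.69 to 13.4) and tRNA genes below (0.391, 0.192 to 0.799). The tRNA share of 5.26% was near the 5.99% of all genes that are not protein-coding. Transcription was not measured here, so these lists do not settle the question. Controls without the tag are not used here, and the design has 1 group, so no biological explanation was tested.

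The region at the Dyro promoter may be strong because the tagged locus is present in extra copies. The gene body test gave a median of 17.6 (percentile 6.79), below the bound set for no effect, but it rested on 2 candidates left after 6 regions passed. It therefore decides nothing, by a minimum of 5 candidates set after that count was seen. Candidates 500 bp to 20 kb from the gene had a median signal of 68.3 against 28.6 in the median window (percentile 99.9 of 4902 windows), and percentiles of 99.8, 99.9 and 99.9 in replicates 1, 2 and 3, as extra copies of the surrounding sequence predict. True binding over the whole stretch, where 14 main-set regions lay and 9 of 5613 windows held as many, would raise them too, and no copy number was measured. The windows moved in steps of 5 kb along all of 3L and were not kept off this locus. Some of the 9, and of the windows above the percentiles, may therefore overlap it and are not shown to be other places.

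A group of 120 main-set regions had a signal under 20 although the main set's median was 132.0. These may be shoulders of stronger neighbours. A stronger candidate overlapped 99.2% of them, against 3.41% of the other 2552 regions and 55.8% of the candidates with a signal under 20 that did not pass. Without them the promoter odds ratio was 5.83. No biological explanation was tested for them.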
